A study of Mus musculus with 36 samples.

How the data were processed

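Expression arrays of mouse intestine were analysed from the deposited tables of values. Per the labels, intestines of 8-week-old male CD-1 mice on standard chow were collected, and each segment was split into 3 pools of 10 mice, which were hybridised as total RNA. The segments were the duodenum (the piece just after the stomach), the jejunum (from the middle of the small intestine), the ileum (the piece before the junction with the caecum) and the undivided colon. Every pool was measured on array sets A, B and C, which gives 4 groups of 3 samples on 36 arrays. The labels do not say whether samples of different segments with the same number come from the same mice, so the numbers were not used as pairs. Array duodenum 3 on array set C carries jejunum in its source name, and it was kept as duodenum by its title. Of 30 probe sets of array set C called at least 2-fold between jejunum and duodenum, 30 placed this sample closer to the other duodenum samples. These were called with the array already counted as duodenum, which favours this placing, so they cannot settle which name is right.

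The deposited values are intensity values on a linear scale, per the values themselves and the labels, which name no unit. In every table the mean without the highest and lowest 2% lay between 200 and 200.2, so the authors scaled the arrays to a common mean. The software and steps used for this are not given in the sources used here. The tables hold 12488, 12477 and 11934 probe sets, with 66 controls each. The 198 controls stayed out of the tests, which left 36701 probe sets (12422, 12411 and 11868). Values ranged from 0.1 to 43400 on array set A, from 0.2 to 65950 on B and from 0.2 to 72320 on C. No detection calls were used, and no array was left out. Over all arrays the ratio of 3' to 5' signal was 1.14 to 1.84, 1.16 to 1.81 and 1.01 to 2.03 for actin and 0.954 to 1.24, 0.890 to 1.25 and 0.936 to 1.33 for Gapdh on array sets A, B and C. The depth of an array is given by its median intensity in the report, and the number of arrays limits the precision.

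From these values log2 of the intensity plus 16 was computed, with the authors' scaling kept. The offset makes differences of dim genes smaller than they were on the linear scale. Each array set was fitted on its own with limma 3.58.1 in R 4.3.3, with 1 mean per segment over all 12 arrays of the set and moderated variances with an intensity trend. Tests were made for jejunum minus duodenum, ileum minus jejunum, colon minus ileum, colon minus the mean of the 3 small-intestinal segments, and any difference among the segments. The p-values of the 3 array sets were adjusted together by the Benjamini-Hochberg method, all tests were 2-sided, and a probe set was called at an adjusted p below 0.05. The p-values measure the spread between pools, and with whole tissue a difference can come from a change within cells or from a change in the mix of cells. The residual SD had a median of 0.36 on array set A, 0.50 on B and 0.55 on C.

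Probe sets were given gene symbols from the annotation provided with the arrays. Of those tested, 29131 carried 1 symbol, 724 several and 6846 none, and 29044 matched a current gene. For gene lists each of 15964 genes was represented by 1 probe set, taken from array set A (8251 genes), else B (5423), else C (2290), and within a set the one with the highest mean. Probe sets of gene families such as the defensins, cytochromes, pancreatic proteases, Reg proteins and kallikreins can bind transcripts of relatives. The 30 gene lists were written before the data were examined, and 4 more (islet, epithelial structure, fibroblast and matrix, endothelium) were chosen after the data were seen. Lists were tested with cameraPR of limma on the moderated t statistics with a preset correlation of 0.01 between genes, and again with a correlation estimated from the residuals, with Benjamini-Hochberg adjustment over the 30 lists of a comparison. Genes of a list are not independent replicates, which the correlation only partly allows for.

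Genes were named by a rule written before the data were examined. In each comparison it takes the 10 largest rises and the 10 largest falls among genes called at least 2-fold whose arrays in the compared groups do not overlap and whose mean in the higher segment is above the median of the array set, without unnamed transcripts. It adds up to 4 members of each list with the smallest adjusted p, and the 26 measured regional markers. This gave 564 results, of which 348 were called. Genes named outside the rule are said to be so.

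The procedure was tested on simulated data with the residual spread of the real arrays. Of 36701 probe sets, 300 were shifted by log2 1 and another 300 by log2 2. For jejunum minus duodenum, 17% of shifts of log2 1 and 69.7% of shifts of log2 2 were called, with 5.80% of calls false. For ileum minus jejunum the shares were 17.7% and 65.3%, with 6.39% false, and for colon minus the small-intestinal mean 32.3% and 81.3%, with 5.28% false. For the latter a 20-gene list shifted by log2 1 had an adjusted p of 1.65e-32, and 0 of 50 lists without a shift were called by limma. The simulated genes varied independently of each other, so this cannot show how the list test behaves with correlated genes.

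Alternatives were quantile normalization, centring each array on its median, offsets of 1 and 64, a filter on low values, adjustment within each array set, no intensity trend, only the arrays of the compared segments, the sample number as a block, each sample left out in turn, array duodenum 3 on array set C left out, the probe set with the median difference of its gene (the lower of 2 middle ones where their number is even), and an estimated correlation for lists. After seeing the data, 3 more were chosen because of the 18S ribosomal RNA control: its class as a block, only the 8 samples with high signal, and only the 4 with low signal for ileum minus jejunum. The upper of 2 middle probe sets was also added then, since the lower one can contradict rises more readily than falls. Differences of list medians were tested by permutation of list membership with 100000 resamples, or exactly where a list had fewer than 10 genes. Image files and probe-level signals were not analysed here.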

Results

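Gene expression was compared along the intestine of adult male CD-1 mice in 4 segments, the duodenum, jejunum, ileum and colon. Each segment was represented by 3 samples, each a pool of intestines from 10 mice, and the small-intestinal segments were taken from the start, the middle and the end of the small intestine. The tissue was the whole segment, so epithelium, immune cells, nerves and muscle all contributed RNA. Every sample was measured on 3 array sets named A, B and C, which gives 36 arrays and 36701 probe sets after the control probe sets were put aside. The trimmed mean of the arrays lay between 200 and 200.2 intensity units, and the median intensity, used here as the measure of signal depth, was 48.6 to 75.3 on array set A, 85.8 to 110.5 on B and 85.9 to 104.9 on C. Correlation between pools of the same segment was 0.932 to 0.970 on array set A, 0.859 to 0.915 on B and 0.817 to 0.904 on C, where the probe sets behind each coefficient are not independent of each other. With 3 pools per segment, the number of arrays limits the precision of every difference.

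Differences between segments were tested with limma on log2 intensities, all tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. The p-values measure the spread between pools, and the genes of a list are not independent replicates. Values are given as mean ± SD of 3 pools in intensity units, beside the log2 difference. The comparisons and the 30 gene lists were fixed before the data were examined. A gene with several probe sets is represented by the brightest of them on array set A, or on B or C where A holds none. In 2 alternatives it is represented instead by the lower or the upper of the middle probe sets when they are ordered by difference, and the upper was added after seeing the data. Where the lower of 2 means lies under the array medians, the probe set is not shown to be above background there, and the size of the log2 difference depends on the offset.

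The 18S ribosomal RNA control divided the samples into 2 classes on all 3 array sets. It was low in jejunum samples 2 and 3 and in ileum samples 1 and 3, at 200.6 to 1541 units on array set A, 851.3 to 3485 on B and 955.4 to 5631 on C. In the other 8 samples it was 5772 to 20058 on A, 14302 to 62810.4 on B and 17053 to 46635 on C. The low class was absent from the duodenum and the colon and held 2 of the 3 samples of both the jejunum and the ileum. The comparison of jejunum with ileum is therefore balanced for the class and the other comparisons are not, and their counts of calls are given below also with the class as a block and among the 8 samples with high 18S signal. Both of these alternatives were chosen after seeing the data. Among the 8 samples the jejunum is represented by jejunum 1 alone and the ileum by ileum 2 alone, so the spread behind those tests comes only from the duodenum and colon pools. The ratio of 3' to 5' signal of actin, a sign of RNA quality, also moved with segment. It was 1.41 to 1.84 in the duodenum and 1.14 to 1.20 in the ileum on array set A, 1.62 to 1.81 and 1.16 to 1.22 on B, and 1.48 to 2.03 and 1.01 to 1.16 on C, with jejunum and colon at 1.20 to 1.61. On every array set the ileum also lay below the jejunum, which began at 1.28, 1.34 and 1.20 on A, B and C. It lay below the colon too, which began at 1.30, 1.35 and 1.25. On B the jejunum, at most 1.55, lay below the duodenum. No result was adjusted for this ratio. The ratio cannot be separated from segment for ileum against jejunum or colon against ileum, nor between duodenum and ileum.

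**Figure D1:**
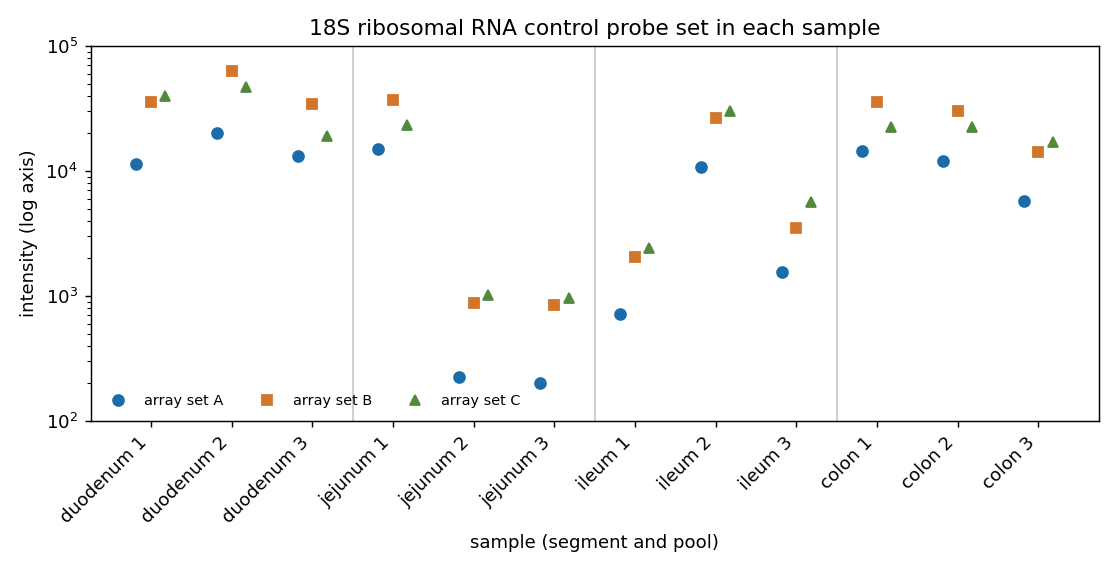
Intensity of the 18S ribosomal RNA control probe set (intensity units, log axis) in each of the 12 samples, with 1 point per sample on each of the array sets A, B and C. Jejunum 2 and 3 and ileum 1 and 3 lie below all other samples, with 200.6 to 1541 units on array set A against 5772 to 20058.

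Genes that differed anywhere along the intestine were asked for first. Expression of 3236 probe sets, 8.82% of those tested, differed between at least some segments (limma, adjusted p below 0.05), with 2011 on array set A (16.2% of that set), 999 on B (8.05%) and 226 on C (1.90%). The count was 3299 with the 18S class as a block and 2206 among the 8 high-18S samples. Between neighbouring segments the number of called probe sets was 339 for jejunum against duodenum, 1020 for ileum against jejunum and 1202 for colon against ileum. The order of the last 2 turned in 5 alternatives, with 1246 and 1140 with the 18S class as a block, 1251 and 1177 after a filter on low values, 1410 and 1339 without jejunum 1, 1114 and 933 without ileum 2, and 847 and 826 without colon 3. Among the 8 high-18S samples the first 2 were 97 and 67. Against the mean of the 3 small-intestinal segments the colon had 2778 called probe sets, a comparison that also uses more pools than the others. Among single genes, Apoa1, which encodes the main protein of high-density lipoprotein, fell from 23510 ± 7510 units in the ileum to 26.9 ± 11.2 in the colon, and Car1, a carbonic anhydrase, rose from 19.3 ± 6.41 to 14650 ± 2470. The lower values lie under the array medians, and with offsets of 1 and 64 the log2 differences between colon and ileum were -9.74 and -7.98 for Apoa1 and 9.54 and 7.46 for Car1.

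**Figure D2:**
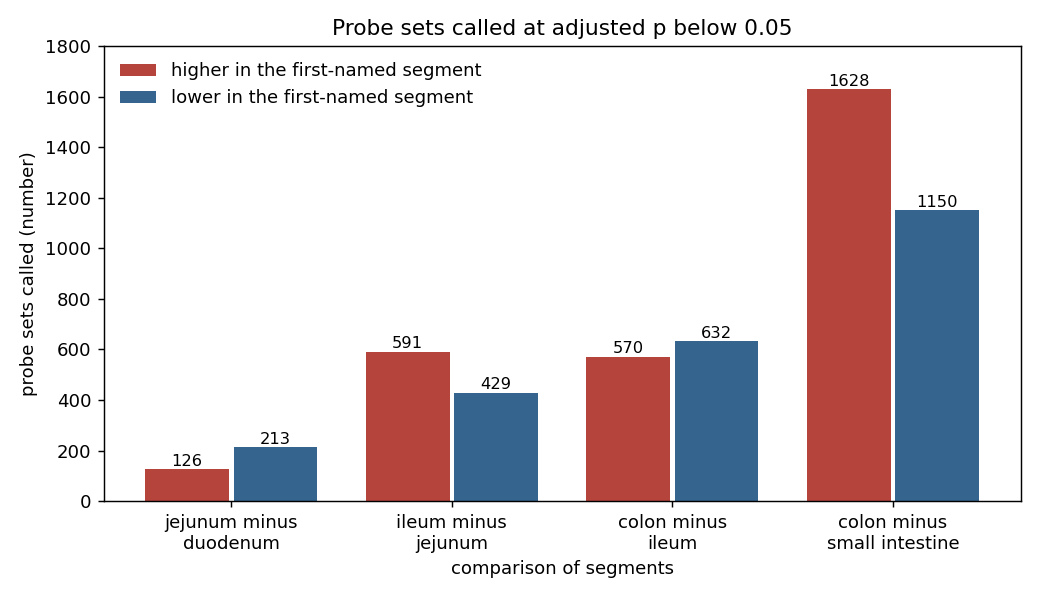
Number of probe sets called higher (left, red bars) or lower (right, blue bars) in each comparison of intestinal segments at an adjusted p below 0.05 (limma, 3 pools per segment). The number was 339 between duodenum and jejunum, 1020 between jejunum and ileum and 1202 between ileum and colon, an order that turned in some alternatives, and 2778 were called for the colon against the mean of the small intestine; after centring each array on its median the split for ileum against jejunum turned from 591 higher and 429 lower to 202 higher and 551 lower.

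How does the jejunum differ from the duodenum? The duodenum samples were set apart by genes of glands and the exocrine pancreas, and the jejunum samples by carriers for sugars, amino acids and peptides. Some gastric and Brunner's gland transcripts, such as Tff2, and most pancreatic enzyme transcripts were abundant in the duodenum and almost gone in the jejunum. Single iron and calcium genes, such as Slc40a1 and S100g, were higher in the duodenum. In all, 126 probe sets were higher in the jejunum and 213 lower.

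Gastric and Brunner's gland markers fell from duodenum to jejunum. Of 12 measured genes 5 were called lower (7 adjusted over the list alone) and none higher, with a list median of -0.92 (adjusted p = 1.56e-11). Tff2, the trefoil peptide of mucous neck and Brunner's gland cells, fell from 18750 ± 3310 to 14.9 ± 14.8 units (log2 -9.34, SE 0.407, adjusted p = 4.33e-09). Gkn3, a gastrokine, fell from 32250 ± 13100 to 91.0 ± 70.9 (-8.35, adjusted p = 1.1e-07, not called with its upper middle probe set at -0.35), and the mucin Muc1 from 440.0 ± 50.6 to 51.5 ± 26.8 (-2.83, adjusted p = 0.000173). Gkn2 fell too, with -3.59 (adjusted p = 0.00079), but its call ended among the 8 high-18S samples, where the value was -3.50. The list median was -0.97 with the 18S class as a block and -1.03 among the high-18S samples. Carried-along stomach tissue was not tested as a source.

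Exocrine pancreas markers had the largest shift of all 30 lists in this comparison. Of 20 measured genes 16 were called lower in the jejunum (17 adjusted over the list alone), with a median of -5.48 (adjusted p = 2.49e-52). The proteases Prss2 (11420 ± 2060 to 8.17 ± 2.42 units, log2 -8.88, adjusted p = 2.98e-08) and Cela3b (15650 ± 1050 to 32.3 ± 8.58, -8.36, SE 0.295, adjusted p = 3.07e-10) and the carboxypeptidase Cpa1 (17140 ± 5860 to 32.0 ± 8.56, -8.44, adjusted p = 9.72e-09) were nearly absent from the jejunum. Not called were Amy2a5 (11.4 ± 4.82 units in the duodenum, 13.0 ± 9.17 in the jejunum), Pnliprp2 (-0.42), Spink1 (-0.68) and Pla2g1b (-1.17, adjusted p = 0.122). With the 18S class as a block 15 genes were called and the median was -5.03.

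Some genes of iron, zinc and calcium handling were lower in the jejunum. Of 17 iron and zinc genes 5 were called lower in the jejunum (2 higher and 6 lower adjusted over the list alone), with a median of -0.12, a mean of -0.76 and a test towards lower (adjusted p = 0.00237). Ferroportin, Slc40a1, which exports iron into the blood, fell from 8017 ± 822 to 168.2 ± 56.1 units (log2 -5.49, SE 0.316, adjusted p = 4.01e-08), and the ferric reductase Cybrd1 from 799.1 ± 107 to 185.9 ± 20.7 (-2.01, adjusted p = 0.000689). The iron importer Slc11a2 fell by 1.73 (adjusted p = 0.00157), and its call ended among the 8 high-18S samples (-1.62) and turned to 0.57 with its other probe set. Centring the arrays on the median turned the sign of the list median to 0.05 with the test still towards lower, and leaving out jejunum 1 (adjusted p = 0.0544) or taking the upper middle probe sets (0.159, with a median of 0.00) ended the call, in a range over the alternatives of 0.000259 to 0.159. With the 18S class as a block 3 of these genes were called and the median was -0.26. Of 8 calcium and vitamin D genes 2 were called lower (4 adjusted over the list alone), with a median of -0.56 (adjusted p = 4.32e-05), or 1 and -0.59 with the class as a block, led by S100g, the calcium-binding calbindin of enterocytes, at 2659 ± 243 against 38.0 ± 18.8 units (-5.69, SE 0.314, adjusted p = 4.86e-08).

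Transporters of sugars, amino acids and peptides rose in the jejunum. Of 20 genes 6 were called higher (8 adjusted over the list alone) and none lower, with a median of 0.42 (adjusted p = 1.73e-07), 0.46 with the 18S class as a block and 0.39 among the high-18S samples. They included the amino acid exchangers Slc7a7 (1253 ± 159 to 3677 ± 1060 units, log2 1.50, adjusted p = 0.000806) and Slc7a8 (1.90, adjusted p = 0.00183), the heavy chain Slc3a2 (1.55, adjusted p = 0.000367) and the proton-coupled carrier Slc36a1 (1.57, adjusted p = 0.00117). The calls of these 4 genes ended among the 8 high-18S samples, where the values were 0.97, 1.31, 1.16 and 1.01, and that of Slc3a2 also ended with another of its probe sets (1.25). Outside the list, the monocarboxylate carrier Slc5a12 rose from 10.2 ± 5.09 to 705.3 ± 210 units (4.76, SE 0.508, adjusted p = 6.52e-05), the dicarboxylate carrier Slc13a2 from 1366 ± 307 to 10260 ± 4030 (2.83, adjusted p = 2.43e-05), and the transcription factor Osr2 from 35.2 ± 7.36 to 714.8 ± 321 (3.76, adjusted p = 2.72e-06).

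Brush-border hydrolases moved both ways between duodenum and jejunum. Aminopeptidase N, Anpep, rose from 3974 ± 391 to 12770 ± 721 units (log2 1.68, adjusted p = 4.59e-05) and angiotensin-converting enzyme, Ace, from 703.3 ± 78.8 to 4631 ± 1270 (2.66, adjusted p = 0.000383). The alkaline phosphatases fell, Akp3 from 7026 ± 1980 to 115.9 ± 133 (-6.19, adjusted p = 2.43e-05) and Alpi from 52060 ± 10300 to 18620 ± 2360 (-1.47, adjusted p = 0.000785). The calls of Ace and Alpi ended among the 8 high-18S samples (2.15 and -1.50), and that of Alpi also with only the arrays of the 2 segments (-1.47). Lactase, Lct, measured 3082 ± 160 units in the duodenum and 8091 ± 691 in the jejunum, but this was not called (1.39, adjusted p = 0.0793). Of the 14 genes of the list 2 were called higher and 2 lower (5 and 3 adjusted over the list alone), its median of 0.50 and mean of -0.04 had opposite signs, and its test was not called (towards higher, adjusted p = 0.094). It was called with an offset of 64 (0.0402) and without jejunum 3 (0.0156), in a range of 0.0156 to 0.446.

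Paneth cell and antimicrobial genes were the last called list for this step. Of 11 genes 2 were called higher in the jejunum (3 adjusted over the list alone), with a median of 0.51 (adjusted p = 0.0138), but adjusted p = 0.116 with an estimated correlation. The antibacterial lectin Reg3a rose from 533.5 ± 246 to 3157 ± 687 units (log2 2.60, adjusted p = 0.000191). The list call also ended without duodenum 3 (adjusted p = 0.135), without jejunum 1 (0.0576), without jejunum 2 (0.0743) and among the 8 high-18S samples (0.168), within a range over the alternatives of 0.00374 to 0.168. The other 24 lists were not called, with adjusted p from 0.094 to 0.954. Of these, lipid absorption (median 0.16, adjusted p = 0.137) was called higher with the 18S class as a block (median 0.46, adjusted p = 0.0456), among the 8 high-18S samples (0.046), without duodenum 3 (0.0462) and without jejunum 3 (0.0322), in a range over the alternatives of 0.0322 to 0.487. The solute carriers (0.197) were called with an estimated correlation (0.00293, range 0.00293 to 0.744), and B and plasma cell genes (0.158) without duodenum 1 (0.0312, range 0.0312 to 0.803). Single genes outside the called lists included the duodenal transcription factor Pdx1, which fell from 97.0 ± 2.98 to 10.2 ± 5.30 units (-2.13, adjusted p = 0.000523, not called among the high-18S samples with -2.07), carbonic anhydrase Car2 (-3.78, adjusted p = 1.04e-07) and the lipoprotein receptor Scarb1 (-2.22, adjusted p = 7.36e-05).

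The number of calls for jejunum against duodenum depended on how the samples were used. It was 208 with the 18S class as a block (61 higher, 147 lower), 97 among the 8 high-18S samples (17 higher, 80 lower), 180 with only the arrays of the 2 segments and 213 without the intensity trend. It was 212 without duodenum 2, 217 without duodenum 3, 184 without jejunum 3 and 854 without jejunum 1. Centring on the median gave 115 higher and 128 lower in place of 126 and 213, and moved the median of all probe sets from -0.06 to 0.07. Of 58 named genes called in this comparison, 47 kept their call with the 18S class as a block and 30 among the 8 high-18S samples, where jejunum 1 alone stands for the jejunum. Of the 6 called lists 6 and 5 did. The rises of Cubn (3.41), which takes up vitamin B12, and Dnase1 (2.67) were called on their brightest probe sets, but the lower middle probe set gave -0.43 and -0.04.

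How does the ileum differ from the jejunum? Transcripts for the recovery of bile acids were higher in the ileum, and those for the handling of fat, sugars and drugs were lower. Genes of cholesterol synthesis, of B cells and of antigen presentation were higher in the ileum. Smooth muscle markers were higher too. In all, 591 probe sets were higher in the ileum and 429 lower.

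Bile acid genes rose in the ileum. Of 10 genes 5 were called higher (6 higher and 1 lower adjusted over the list alone), with a median of 1.22 (adjusted p = 4.32e-07). The ileal bile acid binding protein Fabp6 rose from 49.2 ± 10.1 to 10660 ± 2000 units (log2 7.35, SE 0.285, adjusted p = 4.07e-09), which was the largest rise of this comparison. The basolateral bile acid exporters Slc51a (2266 ± 391 to 7420 ± 850, 1.71, adjusted p = 2.11e-05) and Slc51b (725.9 ± 213 to 2638 ± 582, 1.86, adjusted p = 0.000537) and the hormone Fgf15, which signals bile acid status to the liver (16.8 ± 3.76 to 297.6 ± 145, 3.13, adjusted p = 0.000262), rose with it. The apical uptake carrier Slc10a2 was dim, with 2.30 ± 2.87 units in the jejunum and 51.3 ± 14.6 in the ileum (1.87, adjusted p = 0.00759). The calls of Slc51b, Fgf15 and Slc10a2 ended among the 8 high-18S samples (1.44, 2.00 and 1.85). With the lower middle probe set Fabp6 (0.06) and Slc51a (1.66) were not called.

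Lipid absorption genes fell in the ileum. Of 19 genes 11 were called lower and 1 higher (12 and 1 adjusted over the list alone), with a median of -1.01 (adjusted p = 1.27e-13). The fatty acid binding protein Fabp1 fell from 12520 ± 4860 to 453.1 ± 362 units (log2 -5.18, adjusted p = 0.000115, not called with its upper middle probe set at -0.96), the apolipoprotein Apoc2 from 13400 ± 1540 to 994.9 ± 455 (-3.85, adjusted p = 2.97e-06) and the retinol carrier Rbp2 from 5658 ± 314 to 782.1 ± 204 (-2.86, adjusted p = 1.47e-06). Apoa4, which coats chylomicrons, fell from 21240 ± 4450 to 3147 ± 1730 (-2.92, adjusted p = 0.001), with its call ending among the 8 high-18S samples (-2.48).

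Sugar, amino acid and peptide transporters and brush-border hydrolases fell as well. Of 20 transporters 9 were called lower and 1 higher (9 and 3 adjusted over the list alone), with a median of -0.53 (adjusted p = 6.63e-06). The facilitative glucose carrier Slc2a2 fell from 1598 ± 486 to 113.7 ± 41.3 units (log2 -3.64, adjusted p = 1.57e-06), the sodium-coupled glucose carrier Slc5a1 from 5159 ± 694 to 2289 ± 178 (-1.16, adjusted p = 0.00148) and the fructose carrier Slc2a5 by 2.32 (adjusted p = 0.000746), while the glutamate carrier Slc1a1 rose by 2.39 (adjusted p = 0.00059). Of 14 hydrolases 5 were called lower and 1 higher (the same adjusted over the list alone), with a median of -0.05 (adjusted p = 0.0032) that was -0.93 among the high-18S and -0.14 among the low-18S samples. It turned to 0.06 without jejunum 1, with the test still towards lower. Lct fell from 8091 ± 691 to 1042 ± 379 (-3.01, adjusted p = 0.000174), the trehalase Treh by 2.69 (adjusted p = 7.42e-05) and Ace by 3.13 (adjusted p = 7.18e-05). Among the 8 high-18S samples, only Slc2a2 of these genes stayed called, and the others had values of -1.17 (Slc5a1), -1.84 (Slc2a5), 1.96 (Slc1a1), -2.59 (Lct), -2.25 (Treh) and -2.33 (Ace). Slc2a5 (-0.26) and Slc5a1 (-0.63) also were not called with the upper middle probe set.

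Xenobiotic metabolism had the smallest adjusted p of the lists for this step. Of 44 genes 19 were called lower in the ileum (24 lower and 1 higher adjusted over the list alone), with a median of -0.79 (adjusted p = 6.58e-19). Cytochrome P450 Cyp2b10 fell from 5365 ± 738 to 212.8 ± 58.5 units (log2 -4.58, adjusted p = 8.11e-08), alcohol dehydrogenase Adh1 by 4.01 (adjusted p = 6.63e-07), the glutathione transferase Gstm6 by 3.85 (adjusted p = 2.34e-06) and the epoxide hydrolase Ephx2 by 2.84 (adjusted p = 4.53e-06). Of 14 ketone body and fatty acid oxidation genes 2 were called lower (4 adjusted over the list alone), with a median of -0.43 (adjusted p = 0.0032), but adjusted p = 0.183 with an estimated correlation and 0.0938 among the low-18S samples (range over the alternatives 1.3e-05 to 0.183). Acaa2, a mitochondrial thiolase, fell by 1.35 (adjusted p = 9.03e-05, not called among the high-18S samples with -1.44).

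Cholesterol synthesis, MHC class II and B cell genes rose in the ileum. Of 17 cholesterol synthesis genes 5 were called higher (11 adjusted over the list alone), with a median of 0.86 (adjusted p = 7.14e-08), among them Hmgcs1 (log2 1.99, adjusted p = 0.00064), Sqle (1.84, adjusted p = 0.000171) and Idi1 (2.65, adjusted p = 0.0047). Of 9 MHC class II genes 4 were called higher (7 adjusted over the list alone), with a median of 1.02 (adjusted p = 1.22e-06), and of 16 B and plasma cell genes 3 (12 adjusted over the list alone), with a median of 0.90 (adjusted p = 1.27e-06). The invariant chain Cd74 rose from 4132 ± 412 to 8679 ± 926 units (1.07, adjusted p = 0.00929), H2-DMb1 by 1.24 (adjusted p = 0.00622), and the B cell receptor component Cd79b from 135.2 ± 13.7 to 387.1 ± 82.7 (1.40, adjusted p = 0.00423). Among the 8 high-18S samples these single-gene calls ended, with 1.29 (Hmgcs1), 1.93 (Sqle), 1.52 (Idi1), 1.26 (Cd74), 1.07 (H2-DMb1) and 1.16 (Cd79b). The call of Cd74 also ended after centring on the median (0.79), and that of Idi1 with another probe set (0.20).

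Smooth muscle and goblet cell markers were higher in the ileum than in the jejunum. Of 18 smooth muscle genes 4 were called higher (11 adjusted over the list alone), with a median of 0.71 (adjusted p = 4.76e-06), 0.52 among the high-18S and 0.69 among the low-18S samples. Tagln (log2 0.98, adjusted p = 0.00679) and Cnn1 (0.87, adjusted p = 0.0076), which bind actin in contractile cells, rose, but both calls ended after centring on the median (0.70 and 0.59), with only the arrays of the 2 segments (0.98 and 0.87) and among the high-18S samples (1.16 and 1.21). Fibroblast and matrix genes, a list chosen after the data were seen, had a median of 0.46 that was not called (adjusted p = 0.0511, 0.029 with an estimated correlation, 0.0453 with replicate as a block, 0.0586 with the 18S class as a block), with 2 of 12 genes called higher and 1 lower (5 and 1 adjusted over the list alone). Of 18 goblet cell genes 2 were called higher (4 adjusted over the list alone), with a median of 0.28 (adjusted p = 0.0378), but adjusted p = 0.139 with an estimated correlation. That list's call also ended after centring on the median (0.14, with a median of -0.00), without the intensity trend (0.0608), without jejunum 1 (0.258), without ileum 3 (0.131), among the low-18S samples (0.139) and with the lower (0.0964) or upper (0.073) middle probe sets, in a range of 0.00136 to 0.258. Retnlb, a goblet cell peptide, rose from 1571 ± 279 to 4158 ± 362 units (1.41, adjusted p = 0.000746, not called among the high-18S samples with 1.47).

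Across all 310 solute carriers, 27 were called lower in the ileum and 13 higher (36 and 22 adjusted over the list alone), with a median of -0.06 (adjusted p = 0.0288). This call ended with quantile normalization (0.054), after centring on the median (0.0669), without jejunum 2 (0.0669), without ileum 2 (0.0602), among the high-18S samples (0.297) and with the upper middle probe sets (0.0573, with a median of 0.02), in a range of 1.94e-05 to 0.297. The folate carrier Slc46a1 fell from 2473 ± 959 to 99.4 ± 24.4 units (log2 -4.37, adjusted p = 2.88e-06), and the phosphate carrier Slc34a2 rose from 159.3 ± 47.2 to 2344 ± 423 (3.77, adjusted p = 1.57e-05, not called among the high-18S samples with 3.51). Outside the lists, the membrane protein Tmigd1 rose from 30.1 ± 13.4 to 3347 ± 1690 (6.07, adjusted p = 3.02e-07) and the sulfite oxidase Suox from 275.6 ± 36.9 to 4468 ± 650 (3.94, adjusted p = 8.16e-08). Reg1, a regenerating-family lectin, fell from 3783 ± 2330 to 143.8 ± 34.5 (-4.41, adjusted p = 3.95e-06). Map3k6 rose on its brightest probe set (3.19), but the lower middle probe set gave -0.06.

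The count of 1020 for ileum against jejunum fell to 376 with only the arrays of the 2 segments, 664 without the intensity trend and 67 among the 8 high-18S samples (27 higher, 40 lower), where each of the 2 segments keeps 1 sample. Between the 2 low-18S samples of each segment it was 1577 (1020 higher, 557 lower). It was 1246 with the 18S class as a block and 657 without jejunum 2. Centring on the median gave 202 higher and 551 lower in place of 591 and 429, and moved the median of all probe sets from 0.06 to -0.11, while quantile normalization gave 448 and 381. Falls also outnumbered rises in the 472 calls without jejunum 3 (225 higher, 247 lower), the 503 without ileum 1 (236 and 267), the 384 without ileum 3 (170 and 214) and the 376 with only the arrays of the 2 segments (169 and 207). The balance of rises and falls therefore rests on both the scaling and the samples used. Of 73 named genes called here, 73 kept their call with the 18S class as a block, 68 between the low-18S samples and 19 among the 8 high-18S samples, and of 12 called lists 12, 10 and 11 did. Fabp6, Tmigd1, Suox, Fabp1, Cyp2b10 and Slc46a1 were among the genes called in each of these, the last of which rests on 1 sample per segment.

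How does the colon differ from the ileum? Transcripts for the absorption of fat, peptides, sugars and bile acids were lower in the colon, and so were those of Paneth cell products. Goblet cell genes, electrolyte and water transport genes and smooth muscle genes were higher in the colon. T cell and antigen presentation genes were lower. In all, 570 probe sets were higher in the colon and 632 lower.

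Lipid absorption genes fell from ileum to colon. Of 19 genes 13 were called lower (13 lower and 1 higher adjusted over the list alone), with a median of -2.52 (adjusted p = 1.03e-21). Mttp, which loads lipid onto apolipoprotein B, fell from 262.4 ± 74.0 to 1.40 ± 0.361 units (log2 -3.97, adjusted p = 8.98e-08), and the monoacylglycerol acyltransferase Mogat2 by 3.40 (adjusted p = 1.97e-07). Apoa1, also of this list, had the largest fall of the comparison, from 23510 ± 7510 to 26.9 ± 11.2 units (-9.08, SE 0.258, adjusted p = 6.69e-12).

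Transcripts for the digestion and uptake of peptides and sugars also fell. Of 14 brush-border hydrolases 8 were called lower (10 adjusted over the list alone) and none higher, with a median of -2.05 (adjusted p = 1.25e-20), among them Anpep (12210 ± 2590 to 188.9 ± 25.7 units, log2 -5.89, adjusted p = 6.69e-12), Enpep (-4.16, adjusted p = 6.31e-09, but 0.40 with its other probe set), Treh (-4.39, adjusted p = 7.92e-08) and Lct (-4.46, adjusted p = 7.46e-07). Of 20 transporters 11 were called lower (13 lower and 3 higher adjusted over the list alone), with a median of -1.87 (adjusted p = 2.31e-19). The neutral amino acid carrier Slc6a19 fell from 7011 ± 1950 to 61.0 ± 36.9 (-6.60, adjusted p = 1.99e-09) and the cystine carrier Slc7a9 by 3.87 (adjusted p = 1.39e-09). Of 10 bile acid genes 4 were called lower and 1 higher (5 and 1 adjusted over the list alone), with a median of -0.87 (adjusted p = 3.23e-05). Fabp6 fell to 115.6 ± 13.0 (-6.33, adjusted p = 1.46e-09, not called with its upper middle probe set at -0.10), Slc51a by 2.48 (adjusted p = 8.95e-08) and Fgf15 by 3.02 (adjusted p = 0.000115), while the export pump Abcc3 rose from 842.1 ± 71.5 to 2956 ± 264 (1.79, adjusted p = 6.13e-05).

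Secretory lineages changed in both directions. Of 18 goblet cell genes 7 were called higher and 1 lower in the colon (9 and 2 adjusted over the list alone), with a median of 0.70 (adjusted p = 0.000992). The mucin Muc2 rose from 4045 ± 876 to 22040 ± 4900 units (log2 2.44, adjusted p = 6.89e-06) and Retnlb from 4158 ± 362 to 23120 ± 5560 (2.45, adjusted p = 7.11e-07), while the trefoil peptide Tff3 fell from 18140 ± 3290 to 8311 ± 817 (-1.11, adjusted p = 0.00194, not called with its upper middle probe set at -0.25). Of 11 Paneth cell and antimicrobial genes 5 were called lower and 1 higher (6 and 1 adjusted over the list alone), with a median of -1.30 (adjusted p = 1.08e-06). Lysozyme, Lyz1, fell from 12240 ± 653 to 870.7 ± 184 (-3.81, adjusted p = 1.17e-06, but 0.35 with its other probe set), the protease Mmp7 from 863.9 ± 121 to 22.1 ± 12.7 (-4.57, adjusted p = 1.29e-08), and the defensins Defa35 (23600 ± 6690 to 52.1 ± 32.7, -8.51, adjusted p = 3.48e-11) and Defa23 (-7.95, adjusted p = 4.54e-13), whose probe sets may not separate the members of the defensin family, fell with them. The colonic hormone Insl5 rose from 9.87 ± 0.153 to 853.1 ± 503 (4.84, adjusted p = 1e-05).

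Electrolyte and water transport genes shifted towards the colon. Of 28 genes 9 were called higher and 3 lower (9 and 4 adjusted over the list alone), with a median of 0.21 and a mean of 0.84 (adjusted p = 0.03). Car1 rose from 19.3 ± 6.41 to 14650 ± 2470 units (log2 8.70, SE 0.320, adjusted p = 1.26e-10), Car2 from 43.7 ± 11.9 to 5327 ± 334 (6.50, adjusted p = 6.53e-11), and the water channels Aqp8 from 32.8 ± 16.6 to 919.4 ± 297 (4.27, adjusted p = 2.49e-06) and Aqp4 from 39.4 ± 8.67 to 742.3 ± 191 (3.75, adjusted p = 1.83e-06). The anion exchanger Slc26a6 fell by 5.44 (adjusted p = 8.8e-11). The list call ended with an offset of 1 (adjusted p = 0.0514) and without ileum 2 (0.0601), in a range of 0.00144 to 0.0601. Outside the list, the cytochrome Cyp2c55 (448.2 ± 320 to 31030 ± 12100, 6.27, adjusted p = 5.78e-06), lactoperoxidase, Lpo (7.13, adjusted p = 1.97e-07), and the amino acid carrier Slc6a14 (5.12, adjusted p = 5.55e-05) rose in the colon.

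Smooth muscle genes rose and lymphoid genes fell. Of 18 smooth muscle genes 11 were called higher (16 adjusted over the list alone) and none lower, with a median of 1.11 (adjusted p = 8.17e-16), 1.55 with the 18S class as a block and 1.45 among the high-18S samples. Cnn1 rose from 1014 ± 48.6 to 4027 ± 408 units (log2 1.97, adjusted p = 1.19e-06), Tagln from 1385 ± 98.4 to 4884 ± 507 (1.80, adjusted p = 9.03e-06) and Acta2 by 1.42 (adjusted p = 0.00051, not called with another probe set at 0.40). Of 16 T and cytotoxic cell genes 4 were called lower (8 adjusted over the list alone), with a median of -1.06 (adjusted p = 5.89e-08). Among them were the chemokine Ccl5 (901.9 ± 271 to 57.5 ± 41.7, -3.75, adjusted p = 2.08e-06) and the granzyme Gzma (-2.12, adjusted p = 0.000952, not called with its upper middle probe set at -0.78). Of 9 MHC class II genes 6 were called lower (7 adjusted over the list alone), with a median of -2.07 (adjusted p = 5.5e-14). Their falls included H2-Ab1 (-2.73, adjusted p = 9.02e-07) and Cd74 (8679 ± 926 to 1883 ± 520, -2.23, adjusted p = 3.95e-06). Of 16 B and plasma cell genes 3 were called lower and 1 higher (11 and 1 adjusted over the list alone), with a median of -0.73 (adjusted p = 8e-06). Mzb1 fell by 1.57 (adjusted p = 0.00161, not called with its upper middle probe set at -0.51) and Blnk rose by 1.39 (adjusted p = 4.27e-05).

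The remaining called lists for the colon against the ileum each lost their call in some alternative. Of 33 Hox genes 5 were called higher (7 higher and 1 lower adjusted over the list alone), with a median of 0.39 (adjusted p = 0.0123), but adjusted p = 0.206 with an estimated correlation, 0.112 with the 18S class as a block and 0.316 among the high-18S samples (range 0.000249 to 0.316). Hoxa7 rose from 14.6 ± 3.53 to 218.2 ± 46.6 units (log2 2.92, adjusted p = 1.05e-05) and Hoxb13 by 2.30 (adjusted p = 0.00453, not called among the high-18S samples with 1.94). Of 20 enteric neuron and glia genes 2 were called higher (3 adjusted over the list alone), with a median of 0.34 (adjusted p = 0.0236), but adjusted p = 0.218 with an estimated correlation, 0.192 with the 18S class as a block, 0.48 among the high-18S samples, 0.0616 without ileum 1 and 0.0807 without ileum 3 (range 0.00391 to 0.48). Of 29 cell cycle genes 1 was called lower, with a median of -0.29 (adjusted p = 0.00538) that had adjusted p = 0.0739 with the 18S class as a block, 0.288 among the high-18S samples and 0.0517 with the lower middle probe sets (range 0.000496 to 0.288).

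Cholesterol synthesis, myeloid cells and the regional markers complete the called lists of this step. No cholesterol synthesis gene was called singly by limma, 5 were lower at an unadjusted p below 0.05, and the list median of -0.22 was called (adjusted p = 0.0236), but with adjusted p = 0.255 with an estimated correlation. It was not called without ileum 3 (0.23), without colon 1 (0.236), with the 18S class as a block (0.335), among the high-18S samples (0.297) and with the lower (0.167) or upper (0.315) middle probe sets, in a range of 0.00297 to 0.335. Of 18 macrophage and mast cell genes 2 were called lower and 1 higher (3 and 2 adjusted over the list alone), led by the lysozyme Lyz2 (log2 -2.50, adjusted p = 2.41e-06, but 0.05 with its other probe set), with a median of -0.29 (adjusted p = 0.0455), but adjusted p = 0.255 with an estimated correlation. That call ended in 9 other alternatives, with an offset of 1 (0.0547), without duodenum 2 (0.0545), jejunum 1 (0.0509), ileum 1 (0.126), colon 1 (0.0819) and colon 3 (0.0999), among the high-18S samples (0.23) and with the lower (0.176) or upper (0.718, with a median of 0.03) middle probe sets, in a range of 0.0215 to 0.718. Of the 26 regional markers 7 were called higher and 8 lower (7 and 10 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.0288), but adjusted p = 0.136 with an estimated correlation, 0.0665 with quantile normalization, 0.0583 without ileum 2, 0.118 among the high-18S samples and 0.321 with the upper middle probe sets (range 0.0201 to 0.321).

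No pool moved the number of 1202 calls for the colon against the ileum by more than a factor of 1.5, and it was 1140 with the 18S class as a block and 1080 among the 8 high-18S samples. Of the 1202 calls, 822 were also called with the class as a block and 380 were not. Of 97 named genes called here 84 kept their call with the 18S class as a block and 78 among the high-18S samples, and of 17 called lists 13 and 11 did.

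How does the colon differ from the small intestine as a whole? By list median the largest falls were of brush-border hydrolases, fat absorption genes and nutrient carriers. Goblet cell and smooth muscle genes were higher in the colon. T cell, antigen presentation and drug metabolism genes were lower. In all, 1628 probe sets were higher in the colon and 1150 lower.

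Absorptive genes fell furthest. Of 19 lipid absorption genes 14 were called lower (16 adjusted over the list alone) and none higher, with a median of -2.56 (adjusted p = 2.2e-27). They included Apoa4 (log2 -7.51, adjusted p = 5.94e-10), Fabp1 (-7.15, adjusted p = 4.89e-08, not called with its upper middle probe set at -0.48) and Mttp (-4.64, adjusted p = 6.79e-10). Of 14 brush-border hydrolases 10 were called lower (10 adjusted over the list alone), with a median of -3.01 (adjusted p = 6.28e-19). Anpep (-5.38, adjusted p = 9.98e-13), Treh (-5.98, adjusted p = 6.51e-11) and Alpi (-3.24, adjusted p = 1.25e-09) were among them. Of 20 transporters 14 were called lower and 2 higher (15 and 4 adjusted over the list alone), with a median of -2.15 (adjusted p = 1.69e-17). Slc6a19 (-6.78, adjusted p = 6.04e-11) and Slc7a9 (-3.49, adjusted p = 2.32e-10) fell. Apoa1 fell with an adjusted p of 3.51e-13.

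Among secretory and transport genes, Car1 had the largest rise (log2 8.40, SE 0.261, adjusted p = 1.04e-11). Of 18 goblet cell genes 9 were called higher and 2 lower (11 and 2 adjusted over the list alone), with a median of 0.87 (adjusted p = 0.000234). Those that rose included Retnlb (3.20, adjusted p = 1.46e-09), Muc2 (2.74, adjusted p = 8.5e-08) and the disulfide isomerase Agr2 (1.79, adjusted p = 2.88e-05). Of 11 Paneth cell and antimicrobial genes 5 were called lower and 1 higher (6 and 2 adjusted over the list alone), with a median of -1.04 (adjusted p = 0.000458). Those that fell included Mmp7 (-3.95, adjusted p = 2.59e-09) and Lyz1 (-3.37, adjusted p = 2.66e-07, but 0.36 with its other probe set). With the upper middle probe sets this list's median turned to 0.06, with the test still towards lower. Of 28 electrolyte and water transport genes 10 were called higher and 5 lower (13 and 7 adjusted over the list alone), and the list was not called (median 0.40, adjusted p = 0.0502). It was called with the 18S class as a block (0.0262), among the 8 high-18S samples (0.035) and in other alternatives, in a range of 0.00477 to 0.0852. Among its members, Car2 (4.62, adjusted p = 2.02e-10) and Aqp8 (3.69, adjusted p = 7.15e-07) rose and the guanylin-family peptide Guca2b fell by 3.50 (adjusted p = 2.74e-10).

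Positional and contractile genes rose in the colon. Of 33 Hox genes 9 were called higher (10 adjusted over the list alone) and none lower, with a median of 0.33 (adjusted p = 0.00827), but adjusted p = 0.158 with an estimated correlation. They included Hoxa7 (log2 3.02, adjusted p = 4.32e-07), Hoxb13 (1.93, adjusted p = 0.00181), Hoxb9 (1.81, adjusted p = 0.000114) and Hoxb6 (1.43, adjusted p = 0.000312). Of 21 regional transcription factors 8 were called higher and 3 lower (9 and 4 adjusted over the list alone), with Foxa1 (2.21, adjusted p = 1.4e-05) and Cdx1 (1.18, adjusted p = 2.18e-05) higher and Gata5 (-3.28, adjusted p = 3.75e-08) and Gata4 (-1.53, adjusted p = 0.00294) lower, but the list as a whole was not called (median 0.28, adjusted p = 0.0749). Of 18 smooth muscle genes 15 were called higher (16 adjusted over the list alone), with a median of 1.62 (adjusted p = 1.42e-17). These included Cnn1 (2.61, adjusted p = 2.15e-09), Tagln (2.46, adjusted p = 1.34e-08) and Csrp1 (1.79, adjusted p = 1.19e-05).

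T cell, MHC class II and drug-metabolism genes were lower in the colon than in the small intestine, while B and plasma cell genes (median -0.27, adjusted p = 0.054, range over the alternatives 0.0248 to 0.316) and macrophage and mast cell genes (-0.06, adjusted p = 0.129, range 0.0544 to 0.812) were not called. The B and plasma cell list was called lower in several alternatives, among them the 18S class as a block (0.0283). Of 16 T and cytotoxic cell genes 7 were called lower (9 adjusted over the list alone), with a median of -0.98 (adjusted p = 1.94e-06). Examples are Ccl5 (log2 -3.92, adjusted p = 6.22e-08) and Gzma (-2.65, adjusted p = 6.72e-06, not called with its upper middle probe set at -0.22). Of 9 MHC class II genes 6 were called lower (6 adjusted over the list alone), with a median of -1.39 (adjusted p = 7.47e-07). H2-Ab1 (-2.11, adjusted p = 8.72e-07) and Cd74 (-1.44, adjusted p = 2.66e-05) fell. Of 44 xenobiotic genes 16 were called lower and 6 higher (22 and 8 adjusted over the list alone), with a median of -0.49 (adjusted p = 1.65e-06). Cyp3a11 (-4.73, adjusted p = 8.55e-09) and Cyp2b10 (-3.81, adjusted p = 1.91e-09) fell and Cyp2c55 (5.99, adjusted p = 6.47e-07) rose.

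Exocrine pancreas and gastric gland markers were lower in the colon than in the small-intestinal mean, which contains the duodenum. Of 20 exocrine genes 15 were called lower (16 adjusted over the list alone), with a median of -1.89 (adjusted p = 3.07e-17). Of 12 gastric and Brunner's gland genes 3 were called lower and 1 higher (3 and 2 adjusted over the list alone), with a median of -0.52 (adjusted p = 0.0258), but adjusted p = 0.136 with an estimated correlation and 0.0834 with the upper middle probe sets (range over the alternatives 0.0136 to 0.136). Gkn3 fell by 3.35 (adjusted p = 3.27e-05, not called with its upper middle probe set at -0.14), while Muc1 rose by 1.49 (adjusted p = 0.00167).

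The other called lists for the colon against the small intestine lost their call in some alternatives. Of 17 iron and zinc genes 4 were called lower and 1 higher (5 and 1 adjusted over the list alone), led by the folate and haem carrier Slc46a1 (log2 -4.14, adjusted p = 4.43e-08) and by Cybrd1 (-1.16, adjusted p = 0.00259), with a median of -0.15 (adjusted p = 0.0189), but adjusted p = 0.0544 with an estimated correlation and 0.0514 with quantile normalization (range 0.0054 to 0.0544). Of 17 immediate early and heat shock genes 5 were called higher and 2 lower (8 and 2 adjusted over the list alone), with a median of 0.53 (adjusted p = 0.0455), which had adjusted p = 0.0514 with quantile normalization, 0.0635 after centring on the median, 0.0548 without jejunum 1, 0.054 without ileum 2, 0.0743 without colon 2 and 0.315 with the lower middle probe sets (range 0.00622 to 0.315). Dusp1, a phosphatase of this list, rose by 1.04 (adjusted p = 0.00116), but not with another probe set (0.39). The 310 solute carriers, 54 called lower and 32 higher (59 and 44 adjusted over the list alone), had a median of 0.01, a mean of -0.15 and a test towards lower (adjusted p = 0.0217). For them adjusted p was 0.0507 with the 18S class as a block, where the median was -0.03, and 0.0617 among the high-18S samples, in a range of 4.67e-06 to 0.0617, and the median was -0.05 with quantile normalization and -0.12 after centring.

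The list of regional markers holds 28 genes known for a given stretch of intestine, of which 26 were measured. For the colon against the small intestine 8 were called higher and 11 lower (8 and 13 adjusted over the list alone), with a median of -0.65 (adjusted p = 0.0191), but adjusted p = 0.106 with an estimated correlation, 0.0715 with quantile normalization and 0.064 with the upper middle probe sets (range 0.0132 to 0.106). Lct was highest in the jejunum, Fabp6 in the ileum and Car1 in the colon, with the values given above. The probe sets of Slc26a3, at 9.73 to 50.5 units across the segment means, and of the sucrase-isomaltase gene Sis, at 2823 to 3321, were not called in any comparison.

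**Figure D3:**
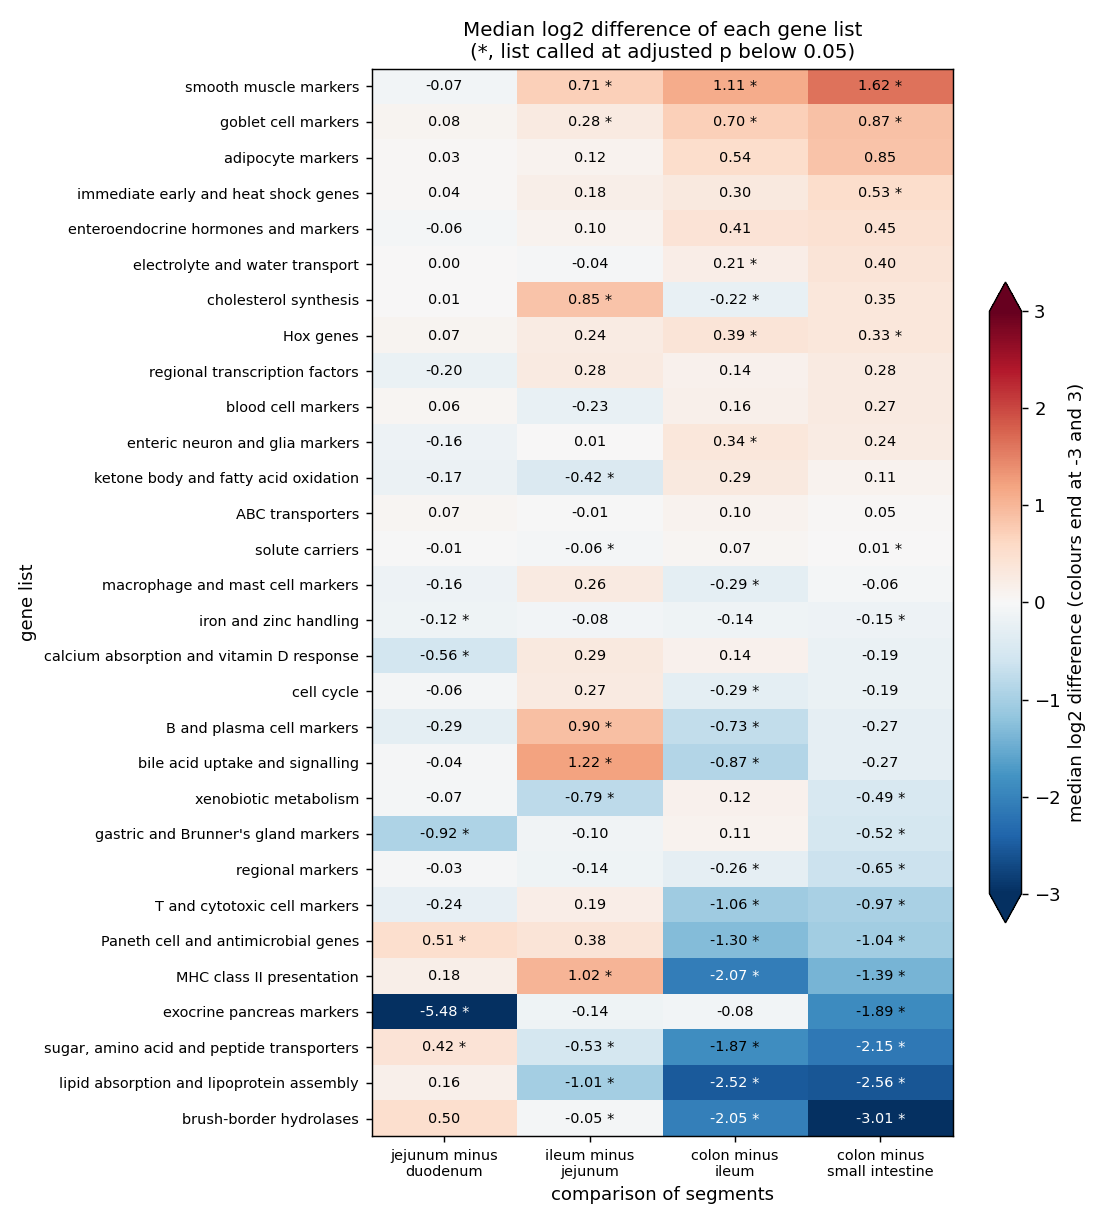
Median log2 difference of 30 gene lists (vertical) in the 4 comparisons of segments (horizontal), with colour for direction and an asterisk where the list test was called at an adjusted p below 0.05. Exocrine pancreas markers have -5.48 for jejunum against duodenum, and smooth muscle markers 1.62 for the colon against the small intestine; the sign of 3 called medians turned under another scaling, to 0.05 for iron and zinc in jejunum against duodenum, to -0.00 for goblet cells in ileum against jejunum and to -0.05 for solute carriers in the colon.

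The count of 2778 for the colon against the small intestine was 1850 without colon 1 and 1745 without colon 3. Centring on the median gave 1050 higher and 1381 lower in place of 1628 and 1150, and moved the median of all probe sets from 0.04 to -0.07. With the 18S class as a block it was 2777, of which 2223 were also called without it, and among the 8 high-18S samples it was 2724. Of 120 named genes called here, 117 kept their call with the class as a block and 116 among the high-18S samples. Of 16 called lists 15 and 15 did.

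Over all 4 comparisons 51 of 120 list results were called, and 39 of them were also called with an estimated correlation between genes. The lists that lost their call with it were those for which that value is given above, and all the lipid, hydrolase, transporter, MHC class II, smooth muscle and xenobiotic results kept it. Of 348 called results of named genes, 182 kept their call in every alternative tried, 290 kept it with the lower and 295 with the upper middle probe set. None of these genes changed direction under another scaling. Of 149 called results of genes with several probe sets, 63 had another probe set called in the same direction and 86 had no other called.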

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

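The tests in this part were chosen only after the results were seen. A control signal stood out in the samples that no comparison above is about. The 18S ribosomal RNA control probe set differed 99.99-fold between the highest and the lowest sample on array set A, 73.8-fold on B and 48.8-fold on C. On each array set the same 4 samples, jejunum 2 and 3 and ileum 1 and 3, had the lowest values. With this class as a term of the limma model, 12 probe sets were called for the class itself (5 higher, 7 lower) at an adjusted p below 0.05, and 4466 had an unadjusted p below 0.05.

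The class lies partly along the segments, so it may contribute to the 339 calls for jejunum against duodenum. With the class as a term, 166 of them kept their call and sign, which excludes the class as the cause of all of them. The other 173 lost their call, with the median absolute log2 difference going from 1.29 to 1.13 and the median SE from 0.260 to 0.295, so a part played by the class cannot be told apart from a loss of precision. Tff2, Cela3b, Slc40a1 and S100g stayed called with the class as a term. A biological origin of the class, such as a difference between groups of mice, was not tested, since the labels carry no such information.

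Pancreatic transcripts were high in the duodenum samples, and pancreas tissue carried along with the duodenum is a candidate explanation. Of 20 exocrine markers, 17 were higher in every duodenum pool than in all 9 other samples, against a chance share of 0.455% for each marker, which tissue carried along and the duodenum's own expression of these genes would both give, so the 2 cannot be told apart. The mean log2 level of the list was 11.5, 11.6 and 11.5 in the duodenum pools and 6.14 to 7.12 in the others. Cross-hybridisation among related enzymes as the whole cause is excluded by the 8 gene families among the called members. Of the markers, Amy2a5, Pla2g1b, Pnliprp2 and Spink1, named after their values were seen, were not called, and Amy2a5 was dim in all segments at 9.33 to 22.3 units.

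Insulin transcripts raise the question of islets in the same tissue. Ins2 fell from 1936 ± 271 units in the duodenum to 2.93 ± 0.577 in the jejunum (log2 -6.68, adjusted p = 7.15e-07, limma), but was not called with its upper middle probe set (-0.04). Of the 5 other islet markers 0 were called by limma (of all 6, 3 were lower at an unadjusted p below 0.05), with duodenum means from 6.57 to 167.6 units, so islets carried along could neither be told from other sources nor excluded.

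Smooth muscle markers were higher in the colon, and a lower share of mucosa in the colon samples might raise every gene of the muscle wall alike. The median log2 difference of the 18 smooth muscle genes exceeded that of the 20 neuron and glia genes by 1.38 (1.62 against 0.24, 2-sided permutation p = 7e-05, adjusted p = 0.000175). These lists therefore did not rise alike. This cannot exclude a lower share of mucosa, since where in the wall the neuron and glia markers were expressed was not measured. Fibroblast and matrix genes also rose (median 0.54), 1.08 below smooth muscle, and endothelium did not (-0.04). More tissue from outside the mucosa stays open as a cause, in part or in whole. Genes are not independent replicates, so the p describes the spread between genes. The authors' scaling as the cause is excluded by the lower of the medians under other scalings, 1.48 after centring on the median against 1.71 with quantile normalization. A thicker muscle layer or more contractile transcript per muscle cell remains open and needs histology or single-cell data.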

How the results depend on the processing

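Counts of called probe sets depended on the choice of samples more than on scaling or offset. For jejunum against duodenum, leaving out single samples gave 184 (without jejunum 3) to 854 (without jejunum 1). For ileum against jejunum the range was 384 (without ileum 3) to 1410 (without jejunum 1). For the colon against the small intestine it was 1745 (without colon 3) to 3064 (without jejunum 1). The colon against the ileum gave 826 to 1339 and any difference 2286 to 3679. Fewer samples leave less precision, but why jejunum 1 raised the counts when left out was not tested.

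With only the arrays of the 2 segments, which leaves fewer residual degrees of freedom, the counts were 180 for jejunum against duodenum and 376 for ileum against jejunum. Without the intensity trend they were 213 and 664, and the cause was not tested. With the 18S class as a block 208 were called for jejunum against duodenum, and among the 8 high-18S samples 97, and 67 for ileum against jejunum, where fewer samples were used. Between the low-18S samples of ileum and jejunum the count was 1577, and the cause was not tested. All other alternatives stayed within 1.5 times of the counts in the report. Quantile normalization gave 269, 829, 1309, 2737 and 3002, an offset of 1 gave 325, 1004, 1124, 2629 and 3101, and an offset of 64 gave 335, 993, 1246, 2966 and 3279, for the 3 steps between neighbours, the colon against the small intestine, and any difference.

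Of 348 called results of named genes, 288 kept their call whichever sample was left out, 318 under both other scalings, 334 with both other offsets, 321 with the 18S class as a block and 182 in every alternative. Of 51 called lists the numbers were 41, 45, 49, 46 and 33. With the array duodenum 3 on array set C left out, 348 genes and 51 lists kept their call. Of 69 list results that were not called, 22 were called in at least 1 alternative (4, 7, 4 and 7 for the 3 steps and for the colon against the small intestine). Counted over pairs of a result and an alternative in which neither was called, the sign changed 152 times for named genes and 156 times for lists.

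The lower of the middle probe sets of a gene turned the sign of 11 called results, and by its construction it can contradict rises more readily than falls. The values were -0.43 for Cubn, -0.0428 for Dnase1, -0.19 for Aqp1 and -0.0389 for Stard4 in jejunum against duodenum. In ileum against jejunum they were -0.0552 for Map3k6, -0.32 for Nts, -0.0455 for Klf4 and -0.49 for Mzb1. Retn had -1.01 against the ileum and -1.41 against the small intestine, and Snap25 -0.29 against the small intestine. The upper of the middle probe sets, added after seeing the data, turned 10. For jejunum against duodenum it gave 0.43 for Pnliprp1, 0.57 for Slc11a2 and again -0.0389 for Stard4, and for ileum against jejunum 0.76 for Ppara. For the colon it gave 0.40 for Enpep, 0.35 for Lyz1 and 0.0526 for Lyz2 against the ileum, and 0.36 for Lyz1, 0.062 for Lyz2 and 0.0622 for Cpt2 against the small intestine. None of these values was called by limma, and the cause was not tested.

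The sample numbers share no pairing in the labels. Same-numbered samples of different segments deviated together with median correlations of -0.02, 0.03 and 0.01 on array sets A, B and C, and 5, 10 and 6 of 12 samples were closest to a sample of their own number. Probe sets within an array are not independent of each other. With the number as a block the counts were 296, 882, 1138, 2615 and 2909. Array set C had the fewest calls and the largest residual spread, so dim genes measured only there are tested with the least precision.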

Other observations

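The 4 added lists, the comparison of the 2 ends of the intestine, the differences between list medians and the regroupings in this part were tests chosen only after the results were seen. The list of enteroendocrine genes was not called in any comparison or alternative, though some of its genes were. For the colon against the small intestine 6 of 23 were called higher and 3 lower (10 and 3 adjusted over the list alone), with a median of 0.45 (limma, adjusted p = 0.129). Insl5 rose by a log2 of 4.71 (adjusted p = 7.45e-07), while Gip, the incretin of the upper intestine, fell by 4.34 (adjusted p = 2.9e-10) and cholecystokinin, Cck, by 2.70 (adjusted p = 1.29e-06). Adipocyte genes were also mixed, with 4 of 9 called higher and 2 lower (5 and 2 adjusted over the list alone) and a median of 0.85 (adjusted p = 0.066). It was called with an estimated correlation (0.000547), after centring on the median (0.0347), with an offset of 64 (0.0487) and with the upper middle probe sets (0.0451), in a range over the alternatives of 0.000547 to 0.345. Against the ileum the adipocyte median was 0.54 (adjusted p = 0.0917), and it was called with an estimated correlation (0.00085), after centring on the median (0.0378), with an offset of 64 (0.0458) and without an intensity trend, in a range of 0.00085 to 0.395. Adiponectin, Adipoq, measured 444.2 ± 82.0 units in the colon against 74.7 ± 42.8 in the ileum (2.96 against the small intestine, adjusted p = 4.72e-06), and Lipe fell by 1.75 (adjusted p = 0.000238).

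Several genes were lower in the jejunum than in the duodenum and higher in the colon than in the ileum. Of 137 genes called lower in the jejunum than in the duodenum and measured for both steps, 39 were also higher in the colon than in the ileum, and 10 were lower in both steps. The reverse, higher in the jejunum and lower in the colon, held for 48 genes, and 2 were higher in both. With the 18S class as a block the 4 numbers were 37, 5, 25 and 1. The 2 comparisons share no arrays but share the error estimate of each probe set, so overlaps are compared with each other and not with a chance value. Examples, chosen after their values were seen, are Muc1 (440.0 ± 50.6, 51.5 ± 26.8, 76.6 ± 28.9 and 378.6 ± 100 units from duodenum to colon) and Car2 (1551 ± 373, 98.7 ± 33.1, 43.7 ± 11.9 and 5327 ± 334). Sycn, a zymogen granule protein, had 1633 ± 333 units in the duodenum, 28.9 ± 10.1 in the jejunum, 19.9 ± 11.5 in the ileum and 1034 ± 380 in the colon.

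Among the 4 lists chosen after the data were seen, fibroblast and matrix genes were higher in the colon than in the small intestine, with 4 of 12 called higher and 1 lower (8 and 1 adjusted over the list alone) and a median of 0.54 (limma, adjusted p = 0.00131), with Sparc at 1.32 and Dcn at 1.10 and Fbln1 at -1.30. Against the ileum they were also higher (median 0.41, adjusted p = 0.0127, but 0.0774 with the 18S class as a block). Epithelial structure genes were lower there (median -0.07, adjusted p = 0.0416, but 0.17 with an estimated correlation). Of 6 islet genes only Ins2, whose fall had been seen, was called lower in the jejunum than in the duodenum. The list test (median -0.62, adjusted p = 0.00173) includes Ins2 and cannot speak for the others. It was not called with the 18S class as a block (median -0.135, adjusted p = 0.0549). Endothelium (median -0.04) and epithelial structure (0.15) were not called for the colon against the small intestine (both adjusted p = 0.872). The smooth muscle median exceeded that of endothelium by 1.66 (2-sided permutation p = 0.00125, adjusted p = 0.00139), of fibroblast genes by 1.08 (p = 0.00067, adjusted p = 0.00112), of epithelial genes by 1.48 (p = 5e-05, adjusted p = 0.000167) and of T cell genes by 2.60 (p = 1e-05, the smallest possible, adjusted p = 5e-05), where genes are not independent replicates. The regional markers Reg3b (15080 to 20630 units across the segment means) and Mt1 (2827 to 5034) were not called in any comparison.

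Whether as many calls could come from any grouping of the samples was tested by regrouping them. For the 3 steps between neighbouring segments only 10 splits of the 6 samples exist, which are too few to judge by. The real split was the 1 of 10 with the most calls each time, with 339 against at most 1 in any other, 1020 against 0 and 1202 against 0 (limma). For the colon against the small intestine the real grouping was the 1 of 100 with the most calls, with 2778 against at most 1419 for a regrouping that kept the 3 colon samples together, and for any difference it was 3236 against at most 786, again 1 of 100. Regroupings mix segments and widen the residual spread, so this cannot exclude chance.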
